A study of Mus musculus with 4 samples.

How the data were processed

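RNA of mouse sciatic nerves at postnatal day 90 was measured on 4 Illumina single-colour bead arrays of 45281 probes, 2 for each of 2 genotypes of Gnmt, the gene of glycine N-methyltransferase. Per the labels, nerves of mice of either sex were pooled before extraction with Trizol and the RNA was amplified and labelled with biotin. The number of mice per pool, and whether the pools of a group came from separate mice, are not given in the sources used here. The p-values then measure the spread between these arrays, which need not be that between mice.

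For all 4 samples the title gives the opposite genotype to the strain, source name and description fields. Groups followed the strain field, and this was fixed before the data were examined. The libraries labelled WT by strain and KO by title are called strain-WT (title-KO), and the libraries labelled KO by strain and WT by title are called strain-KO (title-WT). Every difference is strain-KO minus strain-WT, and every direction is turned if the titles are right. No array was regrouped by its values.

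The deposited intensity values are linear and background-subtracted, with between 31.6% and 33.9% of the values per array at or below 0. A detection p-value was deposited beside each intensity, per the file headers. GenomeStudio and lumi are named in the submitters' processing notes, with no version or role. The authors also deposited log2 values of 17610 probes, which are those with a detection p under 0.01 on at least 1 array. Each log2 column ranks its probes as the intensity column of the same title does, and the sorted log2 columns differ by at most 0.157, as after quantile normalization. The offset added before these log2 values were taken stays unknown. Columns of the intensity table were assigned to samples by title.

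Intensities were background-corrected and quantile normalized on the log2 scale with neqc of limma 3.58.1 in R 4.3.3, using the deposited detection p-values and an offset of 16. Probes with a detection p under 0.05 on at least 2 arrays were kept, which left 18502. The 2 groups were compared with lmFit and eBayes of limma without covariates, and p-values were adjusted by Benjamini-Hochberg over the probes kept, with a threshold of 0.05. The fit had 2 residual degrees of freedom and 4.71 from the prior. Where a probe had a detection p of 0.05 or more on both arrays of a group, the fold is given as a bound. The bound sets the brighter group's mean against the mean, per dim array, of the higher of the probe's own signal and the lowest signal among detected probes.

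Of the probes in the annotation used, 15125 had 1 gene and 7 had several, and none was named from the latter. All of them lie in the authors' log2 table, so a probe outside that table has no name here. Symbols were updated by gene identifier through RefSeq genes of assembly GRCm38.p6 for 15111 probes, and 2478 probes of the authors' log2 table are not named here. Of the probes tested, 14862 had 1 gene name, for 10019 genes. No coordinates are given, because the build behind the array is not given in the sources used here.

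A total of 29 gene lists were fixed before the data were examined, to cover the methyl-donor pathway, Schwann cells, lipids and the other cells a dissected nerve may hold. Of their entries, 354 were tested and 142 have no probe named here, for want of a name or of a detected signal. Lists of at least 3 tested genes were tested with camera of limma at a preset correlation of 0.01, with the brightest probe of each gene, and 28 lists qualified. The count of members past the threshold is given over all probes and adjusted over the list alone. Tests with an estimated correlation and with fry were run beside it. With an estimated correlation, camera takes its p-value from the 2 residual degrees of freedom, which raises it at any correlation. A list that fails there is not thereby shown to owe its shift to correlation between genes. A further 5 lists were chosen after the data were seen.

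The genes named were set by a rule fixed beforehand. They are Gnmt, the 12 genes with the largest difference in each direction among called probes whose groups do not overlap (1 probe per gene, the one with the smallest p), up to 4 members of each list past the threshold over the list alone (or the 2 with the smallest p where none passed), and genes that a closing result concerns. Other names are marked as chosen after their values were seen.

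The procedure was tested on simulated data for the comparison of 2 against 2 arrays, over 18502 probes, with 200 changed probes in each of 10 runs. With variances drawn from the fitted prior, 57.6% of 2-fold and 98.4% of 4-fold changes were recovered, and 4.88% of the calls were unchanged probes. With each probe's own moderated variance, 95.4% and 99.6% were recovered, but 11.7% of the calls were unchanged probes, above the nominal 5%. Which of these is closer to the real arrays was not tested. Noise was drawn independently for each probe, so shifts that many probes share within a group were not simulated. In 20 simulated runs of the list test over 10019 genes, a list shifted by 1 on the log2 scale was called in 20, and 1 of 540 tests of unchanged lists was called; these genes were drawn independently of each other.

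The alternatives covered the background correction, the offset, the scaling, the authors' log2 values, the detection filter, the variance prior, the replicate number as a block, the list test, the probes per gene, and each array left out. Figures were drawn with matplotlib 3.10.9.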

Results

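Sciatic nerves of mice with and without a disrupted Gnmt gene were compared at postnatal day 90, with 2 arrays of pooled nerves per group. Gnmt encodes glycine N-methyltransferase, which uses S-adenosylmethionine to methylate glycine. The series concerns DNA methylation in myelinating Schwann cells, and this part asks which transcripts differ between the genotypes. Between 17786 and 18165 of 45281 probes per array were detected at a detection p under 0.05. Normalized values correlated across probes at r = 0.991 between the strain-WT (title-KO) arrays and 0.977 between the strain-KO (title-WT) arrays, against 0.965 to 0.973 between groups. Probes are not independent replicates, and the number of arrays limits the precision.

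Gnmt, the targeted gene, went against the strain label. In the libraries labelled KO by strain and WT by title, probe ILMN_1238783 read intensities of 105.7 and 93.5, and probe ILMN_2837816 read 179.6 and 163.4. In the libraries labelled WT by strain and KO by title the same probes read 3.8 and -2.1, and 12.2 and 10. The first probe was not detected on either of these arrays (detection p 0.217 and 0.634), and the second had detection p-values of 0.0182 and 0.0406. Gnmt was at least 4.19-fold higher in the strain-KO libraries by the first probe (limma adjusted p = 0.000868) and 2.67 ± 0.14 higher on the log2 scale by the second (SE, adjusted p = 0.000424). Where these probes lie relative to the disrupted part of the gene is not given in the sources used here, and a probe outside that part would not check the labels. All directions that follow are those of the strain field and turn if the titles are right.

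**Figure D1:**
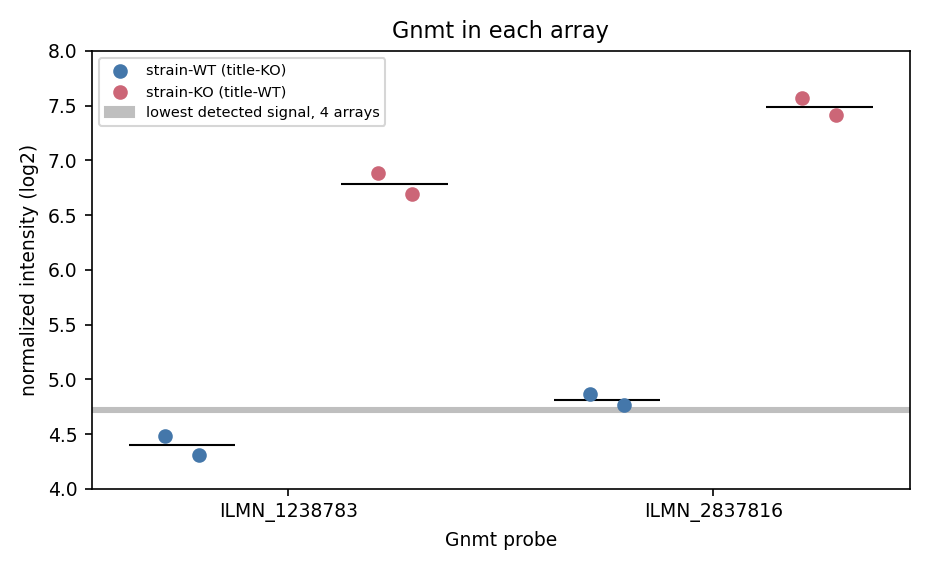
Normalized intensity (log2) of Gnmt probes ILMN_1238783 and ILMN_2837816, with 1 point per array, a line at each group's mean and a grey band at the lowest signal among detected probes of the 4 arrays. Both probes read higher in both strain-KO (title-WT) arrays, by at least 4.19-fold for the first, which was not detected in the strain-WT arrays, and by 2.67 on the log2 scale for the second.

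Fat cell transcripts were higher in the libraries labelled KO by strain, with 13 of 14 adipocyte and 4 of 6 brown adipocyte genes called, as were 13 of 26 genes of oxidative phosphorylation. Called lower were 3 of 13 circadian clock genes, 2 of 17 myelin genes and 1 of 16 Schwann cell regulators. These lists passed as sets at a preset correlation between genes, and 0 of 28 lists passed with an estimated one (lowest adjusted p = 0.282). The latter test rests on 2 degrees of freedom, so few lists could pass it. Of 18502 probes tested, 912 passed an adjusted p of 0.05, of which 646 were higher and 266 lower in the strain-KO libraries. They named 449 genes higher and 204 lower, with 1 gene, Ndufb10, in both. At least 2-fold differences were seen for 358 probes higher and 63 lower. The groups did not overlap for 55.1% of all tested probes, where chance gives 33.3%. The count fell to 175 without strain-WT replicate 1 and to 137 without strain-WT replicate 2, and was 326 with no filter on detection.

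**Figure D2:**
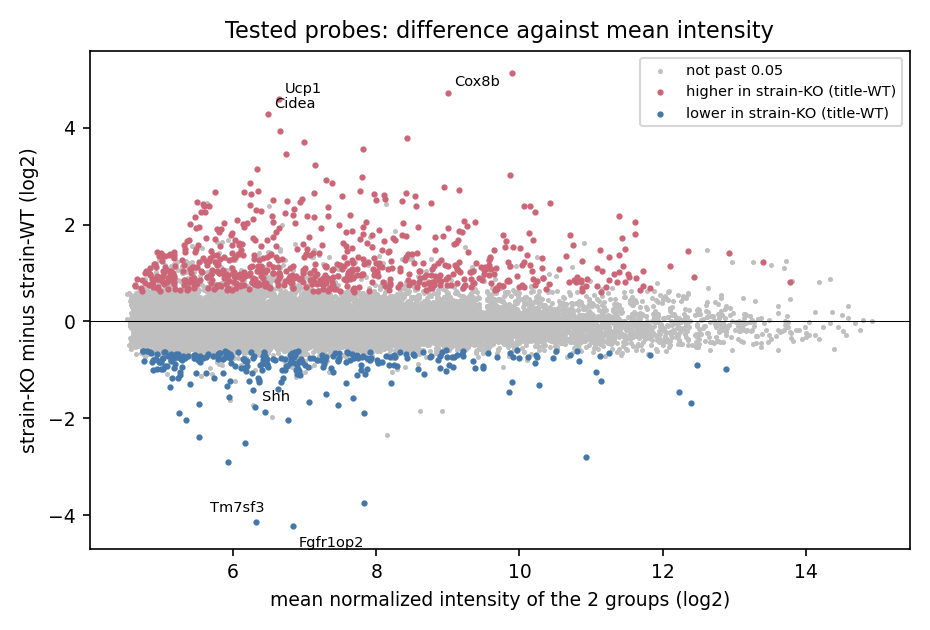
Difference between groups (strain-KO minus strain-WT, log2) against the mean normalized intensity of both groups (log2), with 1 point per tested probe. Coloured points are the 646 probes higher and 266 lower past an adjusted p of 0.05.

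The genes with the largest increases in the strain-KO libraries included several of brown fat. Ucp1, the uncoupling protein of brown fat mitochondria, was at least 18.6-fold higher (adjusted p = 0.000286) and was not detected in either strain-WT array. Cidea, a lipid droplet protein, was at least 15-fold higher. Cox8b, a subunit of cytochrome c oxidase, differed by 4.72 ± 0.35 on the log2 scale (SE, 2 arrays per group). Thrsp, a regulator of lipogenesis, differed by 3.79, Fabp3, a fatty acid binding protein, by 3.45, Ces1d, a carboxylesterase, by 3.01, Apoc1, an apolipoprotein, by 2.98, and Cpt1b, the carnitine palmitoyltransferase of muscle and brown fat, by 2.86. Zfp330 (3.93), Psmd8 (3.70), Man2b1 (3.55) and Pisd-ps3 (3.15) completed the 12. Zfp330 and Pisd-ps3 were detected on 1 of 2 strain-WT arrays, near the lowest detected signal, so their sizes depend on the processing. Over all alternatives they ran from 2.84 to 4.12 and from 2.17 to 3.33. The other tested probe of Zfp330 differed by 0.19 and that of Man2b1 by 0.14, neither past the threshold. Fabp3 read 4.68 and 5.36 in the strain-WT and 7.50 and 9.45 in the strain-KO arrays. Within each group this is the order of the skeletal muscle means (7.38 and 9.35, then 6.86 and 11.6). Its difference ran from 2.47 to 4.43 over all alternatives. Fabp3 did not pass with no filter on detection (adjusted p = 0.128) or with robust eBayes (adjusted p = 0.221). Apoc1 did not pass with no filter on detection (adjusted p = 0.0524, range over all alternatives 3.73e-05 to 0.0524).

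The genes with the largest decreases were led by Fgfr1op2 (-4.23 ± 0.13, SE, adjusted p = 7.29e-05) and Tm7sf3, which was at least 12.9-fold lower in the strain-KO libraries. Ndufb10, a subunit of respiratory complex I, was lower by 1 probe (-3.76) and higher by another (1.94, adjusted p = 0.0017). The other probe of Fgfr1op2 differed by -0.12 and did not pass, and none of 3 other probes of Mcph1 (-1.70) passed in its direction. The named probes of Fgfr1op2 and Mcph1 were detected on 1 of 2 strain-KO arrays, near the lowest detected signal. Their sizes thus depend on the processing, from -4.28 to -3.13 and from -1.76 to -0.98 over all alternatives. Shh, the sonic hedgehog ligand, differed by -1.77, Pglyrp1, a peptidoglycan recognition protein, by -2.04, and Nfkbib, an inhibitor of NF-kappaB, by -1.87. Adgrf5, an adhesion receptor, was at least 3.15-fold lower, and 2900060B14Rik (-2.51), Adat2 (-1.89), 3110021A11Rik (-1.67) and Zfp94 (-1.57) completed the 12. Shh did not pass without strain-WT replicate 1 (adjusted p = 0.157) or replicate 2 (adjusted p = 0.0857), nor Nfkbib without strain-WT replicate 2 (adjusted p = 0.0782), and neither passed with no filter on detection (adjusted p = 0.12 and 0.0651). Over all alternatives the adjusted p ran from 0.000223 to 0.157 for Shh and from 0.00016 to 0.0782 for Nfkbib.

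Of 28 lists tested, 13 were higher and 4 lower in the strain-KO libraries by camera at the preset correlation. With an estimated correlation 0 lists passed, the lowest adjusted p being 0.282. By fry 7 passed, the adipocyte, brown adipocyte, lipid synthesis, oxidative phosphorylation, neutrophil, circadian and methionine lists. The estimated correlation of the lipid synthesis list was 0.00748, below the preset 0.01. Its unadjusted camera p still went from 3.16e-08 to 0.0299, so the loss there came with the 2 degrees of freedom. The adipocyte list rose by a mean of 1.68 on the log2 scale (adjusted p = 1.08e-15 by camera, adjusted p = 0.282 with an estimated correlation). All 14 measured members were higher, and 13 passed over all probes as well as adjusted over the list alone. They included Pparg, the adipogenic nuclear receptor (2.59), Lpl, lipoprotein lipase (2.18), Car3 (2.45) and Adig (2.61). A second Pparg probe differed by 0.35 and did not pass. The brown adipocyte list rose by a mean of 2.65 (adjusted p = 4.58e-06, adjusted p = 0.282 with an estimated correlation), with 4 of 6 members called, among them Cox7a1 (2.39). With Ucp1 and Cidea at their bounds the mean was 2.53. The lowest list mean over all alternatives was 1.76. Adjusted over the list alone, 5 were higher and 1 lower. Of the regulators, Prdm16 was the lower member (-0.54), and Ppargc1a differed by 0.47 and was among the 5 higher. Neither was called over all probes, and Elovl3 was not detected on 2 arrays.

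Lists of lipid synthesis and respiration moved with the fat cell lists. Fatty acid and glycerolipid synthesis rose by a mean of 0.91 (adjusted p = 2.21e-07, adjusted p = 0.282 with an estimated correlation), with 11 of 21 members called higher, and 13 higher and 2 lower adjusted over the list alone. Among them were Mlxipl, a carbohydrate response factor (2.69), Dgat2 (2.38) and Scd1, stearoyl-CoA desaturase (1.42), which did not pass without strain-WT replicate 1 (adjusted p = 0.0532) or replicate 2 (adjusted p = 0.0803). Oxidative phosphorylation rose by a mean of 0.64 (adjusted p = 8.63e-15, adjusted p = 0.282 with an estimated correlation), with 13 of 26 called and 21 adjusted over the list alone, including Ndufa4 (1.24), Cyc1 (1.10) and Cox5a (1.05). Without strain-WT replicate 1 their adjusted p-values were 0.0679, 0.0866 and 0.106, and without strain-WT replicate 2 they were 0.0547, 0.103 and 0.0912. Over all alternatives the lowest adjusted p was 0.000719 for Scd1 and 0.00136, 0.00252 and 0.00264 for these 3, and the highest are those given. Glycolysis rose by 0.39, with 1 of 14 called, Pfkl (0.99), and 3 adjusted over the list alone (adjusted p = 0.418 with an estimated correlation). The glycolysis mean per array was 8.78 and 8.73 in the strain-WT and 8.87 and 9.41 in the strain-KO arrays, and the higher strain-KO array was the one with the higher skeletal muscle mean (11.6 against 6.86). Pfkl did not pass without strain-WT replicate 1 (adjusted p = 0.196), strain-WT replicate 2 (adjusted p = 0.217) or strain-KO replicate 1 (adjusted p = 0.06), or with no filter on detection (adjusted p = 0.109, range over all alternatives 0.00826 to 0.217). The glycolysis mean was 0.66 without strain-KO replicate 1. Without strain-KO replicate 2 it was 0.12 and the list did not pass (adjusted p = 0.279, range over all alternatives 3.60e-06 to 0.418).

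The macrophage list rose by 0.71 (adjusted p = 3.73e-09, adjusted p = 0.418 with an estimated correlation), with all 18 members higher, 5 called over all probes and 15 adjusted over the list alone, including the mannose receptor Mrc1 (1.09), Lyz1 (1.15) and Lyz2 (1.42). In the neutrophil list, S100a8 and S100a9 were called of 3 members, at least 3.43-fold and at least 2.00-fold higher. With these 2 at their bounds the list mean was 1.00, against a fitted 1.17 that fell to 0.63 with offset 50 (adjusted p = 0.418 with an estimated correlation). In the mast cell list (mean 0.83, adjusted p = 0.418 with an estimated correlation) Tpsab1 (2.64) and Kit (1.02) were called of 7. Interferon response genes rose by 0.37 with 1 of 9 called, Oasl2 (0.67), and 5 adjusted over the list alone (adjusted p = 0.418 with an estimated correlation). Without strain-WT replicate 2, Mrc1 (adjusted p = 0.11), Lyz1 (0.147), Lyz2 (0.124), S100a9 (0.0593), Kit (0.193) and Oasl2 (0.3) did not pass. Without strain-WT replicate 1, Mrc1 (adjusted p = 0.0681), Lyz1 (0.0838), S100a9 (0.06), Kit (0.189) and Oasl2 (0.2) did not. Lyz2 (adjusted p = 0.0754), Kit (0.0537) and Oasl2 (0.0698) were also lost without strain-KO replicate 1, and Oasl2 without strain-KO replicate 2 (adjusted p = 0.0816). With no filter on detection Tpsab1, Lyz1, Lyz2, Kit and Oasl2 did not pass (adjusted p = 0.0652, 0.0681, 0.101, 0.101 and 0.0646). Over all alternatives the lowest adjusted p was 0.00283 for Mrc1, 0.00186 for Lyz1, 0.000778 for Lyz2, 0.00108 for S100a9, 2.87e-05 for Tpsab1, 0.00764 for Kit and 0.0224 for Oasl2, and the highest are among those given.

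The endothelial list rose by 0.21, pericytes and smooth muscle by 0.27 and fibroblast and matrix genes by 0.26 (adjusted p = 0.418 each with an estimated correlation). Their called members were Pecam1 (0.86), Tek (0.80) and Tie1 (0.67), then Myh11 (1.46, against -1.27 for Rgs5), then Dpt (1.81) and Fn1 (0.95). Without strain-WT replicate 1, Pecam1 (adjusted p = 0.122), Tek (0.156), Tie1 (0.221), Rgs5 (0.0838) and Fn1 (0.105) did not pass. Without strain-WT replicate 2, Pecam1 (adjusted p = 0.21), Tek (0.209), Tie1 (0.268), Rgs5 (0.0552), Fn1 (0.153) and Myh11 (0.0591) did not. Pecam1 (adjusted p = 0.0553), Tek (0.0532) and Tie1 (0.0784) were also lost without strain-KO replicate 2, and Tie1 without strain-KO replicate 1 (adjusted p = 0.0674). With no filter on detection Pecam1 (adjusted p = 0.0586) and Tie1 (0.0505) did not pass, nor Tie1 with offset 50 (adjusted p = 0.0721). Over all alternatives the lowest adjusted p was 0.0101 for Pecam1, 0.0112 for Tek, 0.0218 for Tie1, 0.00206 for Rgs5, 0.00476 for Fn1 and 0.00062 for Myh11, and the highest are among those given. The endothelial list did not pass without strain-WT replicate 2 (adjusted p = 0.0733), strain-KO replicate 1 (adjusted p = 0.0722) or strain-KO replicate 2 (adjusted p = 0.05), or with median scaling (adjusted p = 0.0518). The pericyte list did not pass without strain-WT replicate 2 (0.24, adjusted p = 0.084) or strain-KO replicate 2 (0.12, adjusted p = 0.198), or with a detection p under 0.01 on all 4 arrays (adjusted p = 0.0523), and its mean was 0.41 without strain-KO replicate 1. Its means per array were 7.46 and 7.41 in the strain-WT and 7.56 and 7.84 in the strain-KO arrays, where the skeletal muscle means were 6.86 and 11.6. The fibroblast list did not pass without strain-KO replicate 1 (0.16, adjusted p = 0.15) or with the mean of all probes of a gene (0.20, adjusted p = 0.0863). The highest adjusted p of each over all alternatives was the 0.418 of the estimated correlation, and the lowest were 0.0204, 0.017 and 0.00859. The heat shock list (0.25, 0 of 10 called over all probes, adjusted p = 0.473 with an estimated correlation) had a mean of 0.03 without strain-KO replicate 1 (adjusted p = 0.342) and 0.13 without strain-WT replicate 2 (adjusted p = 0.212), and passed in neither, nor with median scaling (adjusted p = 0.0518, range over all alternatives 0.00261 to 0.584). Its mean was 0.48 without strain-KO replicate 2. Of the lymphocyte list, 14 of 15 genes have no probe named here, so it was not tested. Such genes may lack a name or a detected signal, and which holds is not known.

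Myelin structure genes were lower by a mean of -0.31 in the strain-KO libraries (adjusted p = 0.00254, adjusted p = 0.418 with an estimated correlation). Of 17 members, Ncmap (-0.90) and Cldn19, a claudin of Schwann cells (-0.73), were called, and 9 were lower and 1 higher adjusted over the list alone, the latter being Pmp2, a fatty acid binding protein of myelin (0.99). Both called members were lost without strain-WT replicate 1 (adjusted p = 0.137 for Ncmap and 0.269 for Cldn19) or replicate 2 (0.154 and 0.272), and Cldn19 also without strain-KO replicate 1 (adjusted p = 0.1) or with no filter on detection (0.101). Their ranges over all alternatives were 0.00438 to 0.154 and 0.0209 to 0.272. Mbp lay near the top of the scale on all arrays (14.79 to 14.84, highest value 14.93), where quantile normalization fixes the values, so its difference says nothing about a change. Schwann cell transcription and signalling genes were lower by -0.24 (adjusted p = 0.0414, adjusted p = 0.418 with an estimated correlation), with Pou3f1, a POU factor of promyelinating Schwann cells, called of 16 (-1.09) and 3 adjusted over the list alone, among them Sox10 (-0.49). Pou3f1 did not pass without strain-WT replicate 1 (adjusted p = 0.146), strain-WT replicate 2 (0.257) or strain-KO replicate 2 (0.0638), or with no filter on detection (0.125, range over all alternatives 0.0117 to 0.257). This list did not pass without strain-KO replicate 2 (adjusted p = 0.147), strain-WT replicate 1 (adjusted p = 0.0549) or strain-WT replicate 2 (adjusted p = 0.057). Cholesterol synthesis genes were lower by -0.23 with 0 of 18 called over all probes or adjusted over the list alone (adjusted p = 0.0268, adjusted p = 0.418 with an estimated correlation), and did not pass without strain-WT replicate 1 (adjusted p = 0.0574) or strain-KO replicate 1 (adjusted p = 0.15). Circadian clock genes were lower by -0.42 (adjusted p = 0.0301, adjusted p = 0.418 with an estimated correlation), with the clock outputs and repressors Dbp (-1.25), Nr1d1 (-1.11) and Ciart (-1.08) called of 13 and 4 adjusted over the list alone. Dbp, Nr1d1 and Ciart did not pass without strain-WT replicate 1 (adjusted p = 0.056, 0.153 and 0.0907) or replicate 2 (0.0783, 0.254 and 0.0978), nor Nr1d1 without strain-KO replicate 1 (0.0674) or with no filter on detection (0.127). Their ranges over all alternatives were 0.00145 to 0.0783, 0.00335 to 0.254 and 0.00267 to 0.0978. Without strain-KO replicate 2 the circadian list did not pass (adjusted p = 0.0744). Over all alternatives the adjusted p of the Schwann cell, cholesterol and circadian lists ran up to 0.418 from 0.0149, 0.00657 and 0.00899.

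The methionine and S-adenosylmethionine list, the pathway of GNMT itself, did not pass by camera (adjusted p = 0.527) and passed by fry (adjusted p = 0.0336, range over all alternatives 0.0336 to 0.944), with a mean of 0.21, a median of -0.03 and Gnmt, Shmt1 (1.22) and Nnmt (0.80) called of 14. Without Gnmt, a choice made after the data were seen, the mean was 0.02 and the list passed neither by camera (adjusted p = 0.944) nor by fry (adjusted p = 0.584). Ahcy, which hydrolyses S-adenosylhomocysteine, was lower adjusted over the list alone (-0.51). The DNA methylation list did not pass (mean -0.02, adjusted p = 0.458), with Gadd45g called of 13 (1.66). The immature and repair Schwann cell list did not pass (adjusted p = 0.252), with Shh, Ncam1 (-0.75) and Gfap (at least 1.38-fold lower) called of 12. Sphingolipid synthesis (-0.18), cell cycle (-0.14), cytosolic ribosome (-0.04), perineurium (-0.02), sex-linked genes (0.01), erythroid genes (0.96) and immediate early genes (0.25, with Egr1 called at 1.06) did not pass either. The immediate early list passed without strain-WT replicate 1 (0.37) or strain-KO replicate 2 (0.54), and its mean was -0.09 without strain-KO replicate 1 and 0.12 without strain-WT replicate 2. The erythroid list mean was 0.29 without strain-WT replicate 2, and the list passed without strain-WT replicate 1 (1.62) or with a detection p under 0.01 on all 4 arrays (0.96, adjusted p = 0.0483, range over all alternatives 8.97e-05 to 0.473) or with the replicate block (adjusted p = 0.00369). Of the called genes, Shmt1, Nnmt, Gadd45g, Ncam1, Gfap and Egr1 did not pass without strain-WT replicate 2 (adjusted p = 0.124, 0.254, 0.112, 0.174, 0.298 and 0.26). Without strain-WT replicate 1, Nnmt, Gadd45g, Ncam1, Gfap and Egr1 did not pass (adjusted p = 0.269, 0.154, 0.261, 0.224 and 0.134). Without strain-KO replicate 1, Shmt1, Nnmt, Ncam1, Gfap and Egr1 did not (adjusted p = 0.0708, 0.0961, 0.0612, 0.0674 and 0.0842), nor Shmt1, Ncam1 and Gfap without strain-KO replicate 2 (adjusted p = 0.0538, 0.0793 and 0.0959). With no filter on detection none of the 6 passed (adjusted p = 0.0929, 0.118, 0.112, 0.0743, 0.0666 and 0.124, in the first order), nor Nnmt with median scaling (adjusted p = 0.0611), nor Gfap with offset 50 (adjusted p = 0.0982) or an intensity trend (adjusted p = 0.0517). Over all alternatives the lowest adjusted p of the 6 was 0.00274, 0.0202, 0.00405, 0.0143, 0.0273 and 0.00322, and the highest are among those given.

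Skeletal muscle genes separated arrays within groups. Their list mean was 7.38 and 9.35 in the strain-WT arrays and 6.86 and 11.6 in the strain-KO arrays, on the log2 scale. Gaps of 1.98 and 4.72 over 17 genes argue against repeat arrays of the same RNA, but do not show separate mice. The list did not pass (mean 0.85, adjusted p = 0.199) and had 0 of 17 members called, but it passed in opposite directions without single arrays, with a mean of 3.20 without strain-KO replicate 1, 1.84 without strain-WT replicate 2 and -1.51 without strain-KO replicate 2. It also passed with the replicate block (adjusted p = 0.000761, range over all alternatives 2.99e-07 to 0.981). The adipocyte list mean was 7.31 and 7.50 against 9.15 and 9.02, and the myelin mean 11.8 and 11.7 against 11.4 and 11.5.

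**Figure D3:**
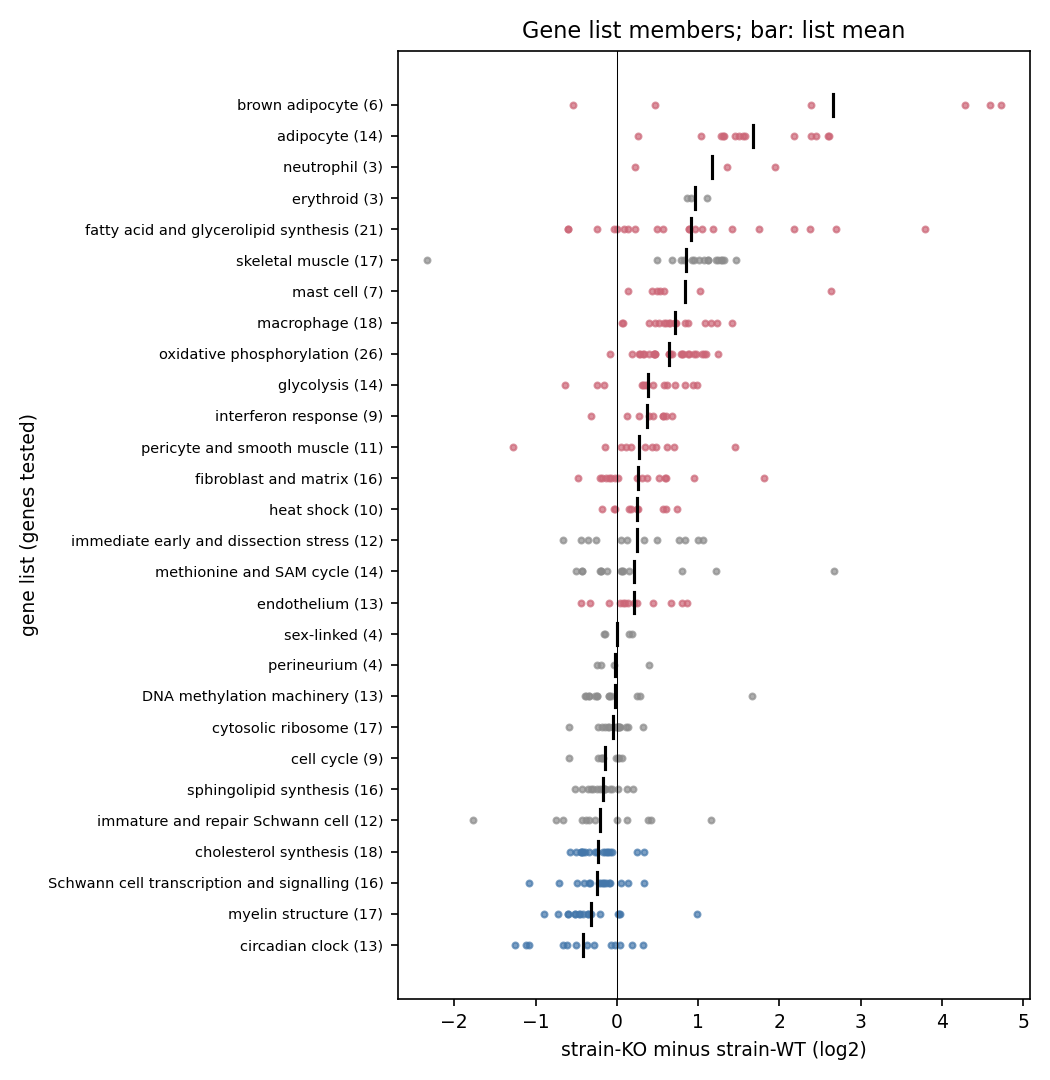
Difference between groups (strain-KO minus strain-WT, log2) of each tested member of the 28 lists, with 1 point per gene and a bar at the list mean. Lists past an adjusted p of 0.05 by camera are red where higher and blue where lower in the strain-KO libraries, and the brown adipocyte list has the highest mean, 2.65.

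**Figure D4:**
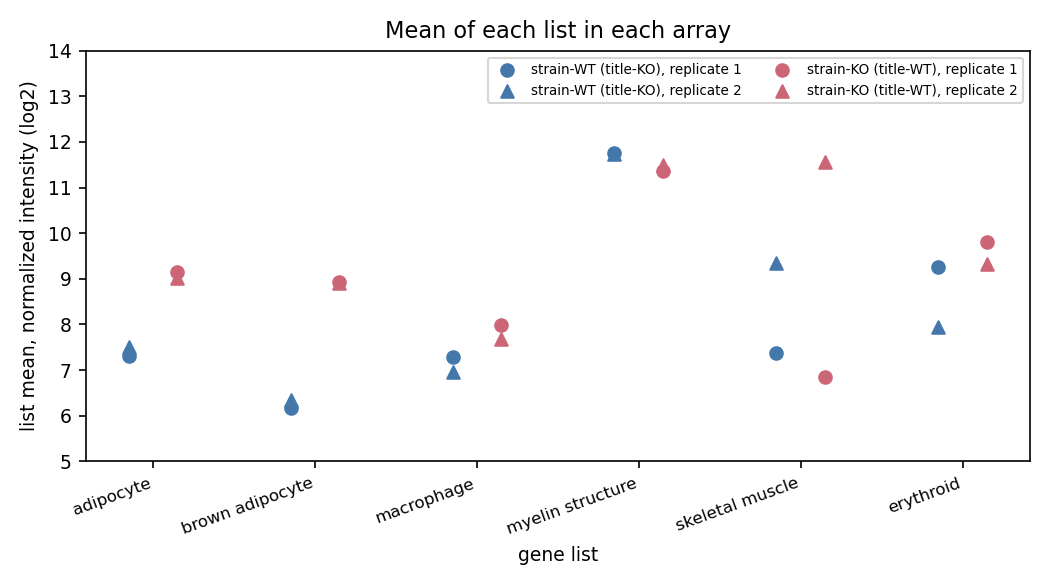
Mean normalized intensity (log2) of 6 gene lists in each of the 4 arrays, with circles for replicate 1 and triangles for replicate 2. The adipocyte means of the groups lie apart, at 7.31 and 7.50 against 9.15 and 9.02, while the skeletal muscle means span 6.86 to 11.6 within the strain-KO group.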

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

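None of the called probes changed direction under any of 15 alternatives, where 724 were tested with a detection p under 0.01 and 548 as the brightest probe of a gene. Alternatives of the detection filter, the variance prior, the replicate block or the probes chosen leave each fitted difference as it was, so they cannot turn a direction. The groups of all 912 called probes do not overlap, so leaving out an array could hardly turn one either. No called list of the 28 changed direction. The skeletal muscle list, not called in the main analysis, was called higher (3.20) or lower (-1.51) depending on the array left out. The 912 called probes (646 higher, 266 lower in strain-KO) became 326, 250 and 76 with no filter on detection, where 45281 probes are tested. Lower calls were 443 with offset 50 and 457 with robust eBayes; the cause was not tested. With the replicate block the counts were 1667, 1058 and 609, with all 912 calls shared and 1 residual degree of freedom, and the skeletal muscle (0.85, adjusted p = 0.000761) and erythroid (0.96, adjusted p = 0.00369) lists were called higher in addition. Same-numbered arrays shared deviations (r = 0.336 across probes), but 2 pairs cannot show pairing. The 92 results for named genes include members past the threshold over their list alone, which had no call over all probes to lose. Of the others, 30 and 34 lost their call without strain-WT replicate 1 and 2, 13 and 8 without strain-KO replicate 1 and 2, and 22 with no filter. Leaving out 1 array at a time gave 137 to 832 probes, 119 to 638 higher and 18 to 194 lower, with fewer arrays and a lone array assumed to vary like the other group. In 5 alternatives added after seeing the data, leaving out probes that differ by over 2 between the strain-KO arrays gave 1341, 867 and 474, a choice that selects probes by their spread. The brightest probe of each named gene gave 575, 411 and 164 of 10019 genes. Leaving adipocyte genes out of the other lists changed no list call. The lipid synthesis list holds no gene of either fat cell list, so its call could not change, and this does not show that other lists are independent of fat. Leaving Gnmt out of the methionine list gave 13 higher and 4 lower by camera and 5 and 1 by fry, since the methionine list then had a mean of 0.02 (adjusted p = 0.944 and 0.584). Of the lists, camera with an estimated correlation called 0 higher and 0 lower and fry 6 higher, the methionine list among them, and 1 lower, against 13 and 4; leaving out arrays gave 11 to 15 higher and 2 to 3 lower. No block by slide was run because the files used here give no slide. Signal over background limits dim genes to bounds.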

Other observations

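Of 5 lists chosen after the data were seen, 3 were higher and 2 lower in the strain-KO (title-WT) libraries by camera at the preset correlation. With an estimated correlation, and so with 2 degrees of freedom, 0 passed. Fatty acid oxidation genes rose by a mean of 1.18 on the log2 scale, with 13 of 18 called, including Cpt1b (2.86), Acaa2 (1.75) and Acadvl (1.77) (adjusted p = 0.122 with an estimated correlation). Genes of the citric acid cycle and pyruvate dehydrogenase rose by 0.85, with 13 of 18 called, including Pdhb (1.60) and the pyruvate carboxylase Pcx (1.13) (adjusted p = 0.076 with an estimated correlation). Glycogen genes rose by a mean of 0.68 (median 0.40), with 5 of 17 called, including the glycogen phosphorylase Pygl (2.59) (adjusted p = 0.185 with an estimated correlation). The glycogen mean per array was 6.97 and 7.12 in the strain-WT and 7.51 and 7.94 in the strain-KO arrays, within each group in the order of the skeletal muscle means (7.38 and 9.35, then 6.86 and 11.6). It differed by 0.47 without strain-KO replicate 2 (adjusted p = 0.0274, range over the alternatives run 1.03e-06 to 0.185). Potassium channel genes were lower by a mean of -0.18 (median -0.39, and a mean of -0.53 over the 9 genes with a detection p under 0.01 on all 4 arrays). Of 12, 4 were called lower, including Kcna1 (-0.73) and Kcna2 (-0.69), and Kcnk3 was called higher (1.90) (adjusted p = 0.277 with an estimated correlation). Whole-nerve RNA does not show which cells these transcripts, or those of the next list, came from. This list did not pass without strain-KO replicate 2 (adjusted p = 0.0645, range over the alternatives run 0.000267 to 0.277). Neuronal and axonal genes were lower by a mean of -0.37 (median -0.52), with 1 of 6 called, Uchl1 (-0.71) (adjusted p = 0.215 with an estimated correlation). They did not pass without strain-WT replicate 1 (adjusted p = 0.0588), without strain-KO replicate 2 (adjusted p = 0.101) or with the mean of all probes of a gene (adjusted p = 0.0592, range over the alternatives run 0.0283 to 0.215).

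Of the tests below, the rule for adjacent genes was written before any result on neighbours, but it was applied only after a wider window, which departs from it, had been tried and had not passed. The other tests were chosen after their results were seen. The genotype stays open throughout as a biological explanation, untested.

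Gnmt signal lay in the arrays whose strain field reads KO. An exchange of the strain, source name and description fields between the groups needs all 8 readings on the side the titles give, and 8 of 8 lay there with a detection p of 0.01 as the limit. The conflict between the label fields was known, and Gnmt was set as its check, before the data were examined. The limit of 0.01 was set after the readings were seen, so the count of 8 restates them. With 0.05, the limit used elsewhere, 6 of 8 lay on that side, since the second probe was weakly detected in both title-KO arrays. The exchange stays open. A transcript left by the disrupted allele and carried by fat tissue could not be told apart. The larger Gnmt difference exceeded the adipocyte mean by 0.996, within 2 SD of that list, and the probes' place in the gene is unknown.

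Fat cell genes were higher in the strain-KO arrays. A lower share of Schwann cells alone would raise other cell types alike. The adipocyte mean exceeded that of 40 endothelial, pericyte and fibroblast genes by 1.43. The SE of this excess (0.2) is over genes taken as independent, not over pools, and is too small if genes vary together. Between pools of a group, the list means differed by at most 0.189 (adipocyte), 0.061 (endothelial), 0.278 (pericyte) and 0.212 (fibroblast). The excess of 1.43 is larger than each of these, which argues against a lower share of Schwann cells alone. That 14 of 14 adipocyte genes were higher restates the pattern, so more adipose tissue in the dissected pools and a change of expression in the fat present cannot be told apart. Chance variation in dissected fat stays open too with 2 pools per group, although the adipocyte mean differed by at most 0.189 within a group against 1.68 between groups. Shares of fat and of other lists such as respiration may overlap, and how far fat accounts for those lists was not tested.

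Some probes differed greatly where other probes of the same gene did not. Among 25 genes with a called 4-fold probe and another tested probe, 32% (8 genes) had no other probe sharing the change, between the limits set for and against sequence or transcript differences under single probes, which stay open. By direction these were 2 of 2 genes lower in strain-KO, Fgfr1op2 and Ndufb10, and 6 of 23 higher. Chromosome segments of another mouse strain may also contribute. A window of 10 genes on each side, run first, held 11 genes with called 4-fold probes near another, against a 95th percentile of 12 (permutation p = 0.112, one-sided). By the rule for adjacent genes, run second on the same data, 4 lay next to another in gene order (GRCm38.p6), against a 95th percentile of 3 in 10000 random draws (permutation p = 0.0485, one-sided, not adjusted for the 2 tests). These are 2 pairs, Fgfr1op2 with Tm7sf3 and Ces1d with Ces1f, and the latter are related carboxylesterases, so the result rests on few genes. Among 100 tested genes around Gnmt, 12 were called where 6.48 were expected (exact hypergeometric test, one-sided p = 0.0279), in a window chosen after the data were seen. Of these, 5 were higher, among them Plin4 of the adipocyte list, Plin5, a lipid droplet gene, and Trem2, a macrophage gene, as the fat cell and macrophage lists were. The other 7 were lower, among them Adgrf5 (at least 3.15-fold), and a segment around Gnmt stays open.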
